A study of Mus musculus with 4 samples.

How the data were processed

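RNA was sequenced from the uterus and the ovary of pregnant mice at embryonic day 3.5, shortly before implantation. The labels give 4 groups, uterus and ovary under low oxygen (hypoxia) or normal oxygen (normoxia), with the low-oxygen exposure placed 72 hours after fertilization. RNA from 3 samples was pooled per group, so each group is 1 library and no spread between animals can be estimated. Per the labels' protocols, RNA was extracted with the reagent ISOGEN II, polyadenylated RNA was captured on magnetic beads, and strand-specific libraries were built.

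The submitters' processing notes name FastQC 0.73, HISAT2 2.2.1, HTSeq 0.9.1 and DESeq2 2.11.40.7, and the mouse build mm10. Which counting options were used, including strand, is not given in the sources used here. For each tissue the authors deposited a gene list with a chromosome, a transcript class and a log2 fold change, per the file headers. The lists hold only genes with an absolute log2 fold change of at least 2, the threshold of the study, and no levels, read totals or p-values. Sequencing depth is therefore unknown. The lists do not state which condition was divided by which. Positive values were taken as higher in hypoxia, an assumption on which each direction given here rests.

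The fold changes were examined for what they imply about the size of the numbers behind them. After division by 1 factor shared within a tissue, 0.995 in the uterus and 0.952 in the ovary, the ratio of every listed gene was a ratio of whole numbers. The tolerance was 5e-14 in relative terms, and the largest relative error was 6.88e-15 in the uterus and 7.77e-15 in the ovary. These whole numbers are called terms, hypoxia first. The terms were read as read counts with 1 added, which is an inference and not stated by any source. Terms come out in lowest form, so a factor common to both is lost and the counts behind them can be larger. Exact Clopper-Pearson intervals of 95% were computed from the terms less 1 and cover counting error only. A gene was called beyond counting error when a two-sided exact binomial test of the terms less 1 passed 0.05 after Bonferroni correction over the 55536 annotated genes. Such a test compares the 2 libraries, not the conditions. A second reading, with the terms themselves as counts, was run as an alternative.

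Gene positions came from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, matched by symbol and chromosome. A position was found for 864 uterus genes and 800 ovary genes. For genes in families of near-identical copies, such as the Sprr2, keratin, Cyp3a, immunoglobulin and histone genes, the authors' counting could have split or discarded reads, and their values are uncertain.

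Before the data were examined, 34 gene lists for pathways and cell types, the threshold alternatives and the rule for named genes were fixed. The rule took the 10 largest fold changes in each direction per tissue, leaving out unnamed gene models and immunoglobulin or T cell receptor genes. It added up to 4 members of each list with at least 3 members listed, every listed member of the low-oxygen list and of the tissue's hormone list, and the 10 shared genes with the largest smaller change. Other genes named were chosen after their values were seen and are said to be so. For a list with at least 3 listed members, the median log2 fold change was placed as a percentile among 10000 random draws of the same size from that tissue's listed genes. Matching on mean level was planned but the lists give no level. Draws matched on the sum of the terms in 5 bins, and the number of members higher, were added after the data were seen.

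The steps were tested on simulated data, and the list percentiles on draws from the deposited values. All 801 simulated uterus genes and all 778 simulated ovary genes had their whole-number pair recovered (100%). Of the genes in these simulated lists, 12.6% in the uterus and 13.4% in the ovary were truly changed, and the rest passed the threshold by counting error. These shares followed from the changed genes and read levels put into the simulation, so they do not estimate the shares in the deposited lists. Both simulations used the same simulated counts and differed in the shared factor. In those simulations 88.9% of uterus pairs and 87.8% of ovary pairs were already in lowest form. Lists of 8 genes were drawn only from the higher genes of each deposited list. They passed percentile 97.5 by the median in 17% of uterus draws and 19% of ovary draws, so the median percentile has little power in these lists. By the number of members higher, 100% of such lists passed in both tissues. That was fixed in advance, because every drawn member was higher, so it does not measure power. By the number of members higher, 5 of the 8 lists with at least 3 listed members were too short to leave the central 95% of draws. A search for ribosomal RNA sequence in 2 genes used BLAST 2.17.0. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.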

Results

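Uterus and ovary were collected at embryonic day 3.5 from pregnant mice kept under low or normal oxygen, to ask how low oxygen alters both tissues around the time of implantation. Each of the 4 groups was 1 pooled library, so no difference below has a replicate check. The authors' deposited tables listed 903 genes in the uterus and 854 in the ovary, and library totals are not given in the sources used here. Positive values are described as higher in hypoxia, a sign that the tables do not state.

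In the authors' deposited table for the uterus, Ltf, which encodes the iron-binding secreted protein lactoferrin, had a log2 fold change of 3.23, and Lcn2, which encodes the siderophore-binding protein lipocalin 2, had 4.03. The Ltf ratio rested on terms of 16403 to 1740, with a counting interval of 8.93 to 9.87 for the fold. The cornified envelope genes Sprr2d, Sprr2b and Sprr2g had 5.42, 5.24 and 3.77 in the authors' deposited table. Sprr2d and Sprr2b rested on terms of 43 to 1 and 38 to 1. By the reading used here that is 0 reads in normoxia, unless a common factor was lost. With a pseudocount of 5 these 2 genes had 3.23 and 3.06, below Sprr2g at 3.67. On the negative side, the authors' deposited table gave Krt83, a hair keratin, -5.03 and Sele, the endothelial adhesion molecule E-selectin, -4.24.

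Of the 36 estrogen-response genes fixed for the uterus, 8 were listed, 6 higher and 2 lower, and 7 of the 8 differed beyond counting error. Their median stood at percentile 99.99 of random draws, while the count of 6 higher stood at percentile 86.2. The draws treated each listed Sprr2 gene as a separate gene though the family has near-identical copies, so 99.99 can overstate how unusual the list was. The higher members were Ltf, Lcn2, the 3 Sprr2 genes above and Clca1, which is linked to mucus secretion. The lower members were Fgf9, at -2.08 in the authors' deposited table, and Sprr2e, at -2.01 on terms of 1 to 4. Clca1, Fgf9 and Sprr2e were named after their values were seen. Lcn2 and Ltf also belong to the neutrophil list, and Lcn2 to the glucocorticoid-response list.

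All 7 listed members of the 23 neutrophil markers were higher, 4 of them beyond counting error. The count stood at percentile 99.2, about the highest that a list of this size can reach. The median of the 7 stood at percentile 83.8. The 4 were S100a8, S100a9, Ltf and Lcn2, of which Ltf and Lcn2 also belong to the estrogen-response list. No percentile was computed without Ltf and Lcn2. Besides Ltf and Lcn2, the authors' deposited table gave Stfa2l1 2.99 and the chemokine receptor Cxcr2 2.36, on terms of 8 to 1 and 31 to 6, neither beyond counting error. The calprotectin genes S100a8 and S100a9 had 2.30 and 2.04 in the authors' deposited table, and with Fpr2 they were named after their values were seen. All 4 listed members of the 19 B and plasma cell markers were also higher and beyond counting error, with the median at percentile 64.0. In the authors' deposited table the immunoglobulin A heavy chain gene Igha had 2.05, the kappa constant gene Igkc 2.19 and the lambda constant gene Iglc1 3.06. The joining chain gene Jchain was higher on terms of 1092 to 251. By transcript class, a set chosen after the values were seen, 52 immunoglobulin genes were listed in the uterus, 50 higher and 2 lower, with 11 of the higher and 1 of the lower, Igkv5-39, beyond counting error. In the ovary 13 were listed, 11 higher and 2 lower, and 1 of them, Ighg3, was higher beyond counting error.

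The 3 listed members of the 34 inflammatory cytokine and chemokine genes were higher and beyond counting error. Ccl28, a mucosal chemokine that attracts cells secreting immunoglobulin A, had 2.89 in the authors' deposited table, Ccl17 had 2.17 and the acute-phase gene Saa3 had 2.05. Their median stood at percentile 55.1. Of the 20 uterine gland genes, 3 were listed, with the median at percentile 21.3. The authors' deposited table gave the secreted protease inhibitor genes Spink1 and Wfdc3 -2.12 and -2.22, both beyond counting error, and Guca2a 2.32 on terms of 5 to 1, whose counting interval included a ratio of 1. Of the 34 progesterone-response genes, 1 was listed, Cyp26a1, which encodes an enzyme that degrades retinoic acid, at 2.26 in the authors' deposited table. None of the 47 low-oxygen response genes was listed (0 genes), which leaves smaller changes unseen.

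Among the 10 largest positive values, the authors' deposited table also held the gasdermin gene Gsdmc2 at 5.58, Accsl at 4.99, the neurofilament gene Nefm at 4.85, the interleukin-36 gene Il1f6 at 4.77, Tinag at 4.75, Kif12 at 4.58, the matrix protease gene Mmp7 at 4.15 and Lypd2 at 4.16. Among the 10 largest negative values it held, per the authors' deposited table, the pancreatic carboxypeptidase gene Cpa1 at -4.71, the cardiac actin gene Actc1 at -4.47, Vmn1r39 and Isx at -4.09, H4c3 at -4.01, Tmprss11g at -3.89, and Bhmt2 and Krt78 at -3.81. Gsdmc2, Accsl, Nefm, Tinag, Kif12, Cpa1 and Actc1 rested on a term of 1, so their sizes and ranks were not fixed. With a pseudocount of 5 they had 3.37, 2.84, 2.72, 2.63, 2.48, -2.59 and -2.39, Mmp7 had 3.55 and Il1f6 had 3.29. With the same pseudocount Lypd2 had 2.13, and Vmn1r39, Isx, H4c3, Bhmt2 and Krt78 lay between -2.08 and -1.85. Of the genes in both groups, Lypd2, Vmn1r39, Isx, H4c3, Bhmt2 and Krt78 did not differ beyond counting error. Some genes with large terms were named after their values were seen. The authors' deposited table gave Mfap4, a microfibril-associated gene, 2.50, the anion exchanger gene Slc26a7 2.40, Cdh16 3.68, and the carbonic anhydrase gene Car4 -2.38.

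On GRCm38, Ltf lies on chromosome 9 from 111019271 to 111042767 and Lcn2 on chromosome 2 from 32384633 to 32388252. Sprr2b, Sprr2d and Sprr2g lie on chromosome 3 between 92316620 and 92375229. The authors' deposited table classes Sprr2g as a polymorphic pseudogene. Igha lies on chromosome 12 from 113254830 to 113260236, and Cyp26a1 on chromosome 19 from 37697798 to 37701536.

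In all, 491 uterus genes were higher and 412 lower, and 337 were protein coding. In 604 genes (66.9%) a term was 1, the median sum of terms was 8, and 113 genes differed beyond counting error, 69 higher and 44 lower. A ratio of 1 to 4 was listed for 139 genes, all lower, because 4 to 1 gave a log2 value of 1.99, short of the threshold; without them 64.3% of genes were higher, against 54.4%. Of the 34 lists, 17 had no listed member, 12 had 1 or 2 and 5 had 3 or more. The lists with 1 or 2 members held Mmp7, Sele, Cyp26a1 and Lcn2, named by rule, and Il11, Nr5a1, Slc4a1, Ifi44l, Mmp12, Scnn1g, Car4, Dnah9, Lep and Serpina1b, genes named after their values were seen.

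**Figure D1:**
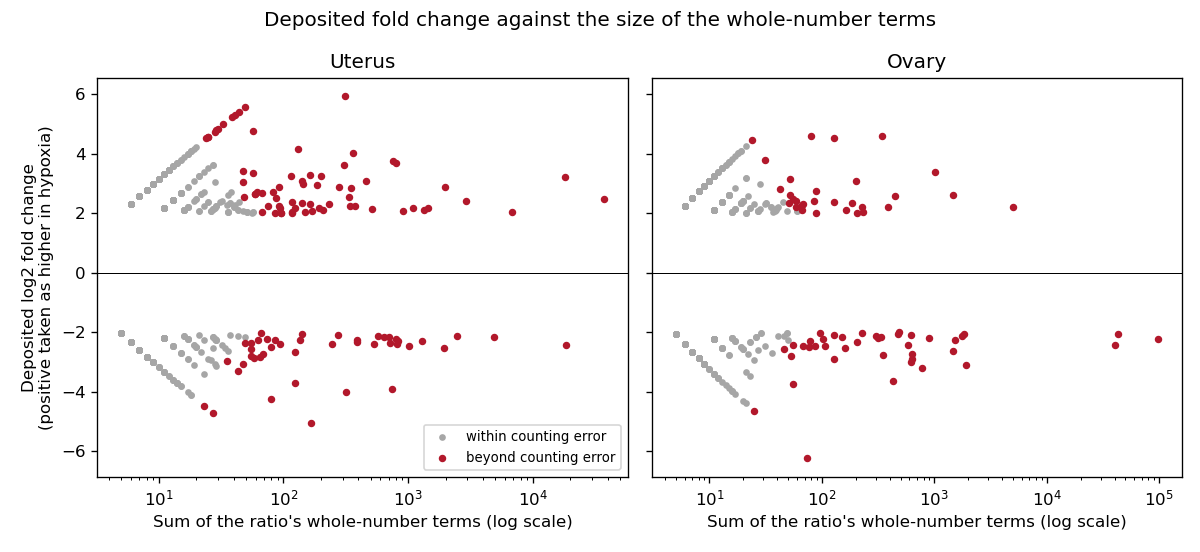
Deposited log2 fold change (y axis, positive taken as higher in hypoxia) against the sum of the whole-number terms of the ratio (x axis, log scale), 1 point per listed gene, uterus at left and ovary at right. The red points are the 113 uterus genes and 71 ovary genes beyond counting error, and grey points are the rest.

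In the authors' deposited table for the ovary, Cyp19a1, which encodes the aromatase that makes estrogens in granulosa cells, had -3.11, on terms of 207 to 1700. Its counting interval for the fold, normoxia over hypoxia, was 7.49 to 10.1. Cyp11b1, which encodes the last enzyme of corticosterone synthesis in the adrenal cortex, had -6.24 in the authors' deposited table on terms of 1 to 72. Its hypoxia term stands for 0 reads by the reading used here, unless a common factor was lost. The size was therefore not fixed, and with a pseudocount of 5 Cyp11b1 had -4.00. Cyp19a1 was the 1 listed member of the 32 steroid synthesis and luteal genes, a list without Cyp11b1. On the positive side, the authors' deposited table gave the milk casein genes Csn1s2a and Csn2 4.55 and 4.10, of which Csn1s2a differed beyond counting error.

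All 4 listed members of the 21 squamous and urothelial markers were lower, 3 of them beyond counting error. The authors' deposited table gave the keratin genes Krt6a -4.07, Krt14 -3.20, Krt5 -2.73 and Krt1 -2.51. Krt6a, on terms of 1 to 16, was the member that did not pass the corrected test for counting error. Their median of -2.96 in the authors' deposited table stood at percentile 0.33. With draws matched on the sum of the terms, the median stood at percentile 1.7. The count of members higher stood at 2.86, about the lowest that a list of this size can reach. The draws treated the keratin genes, a family with near-identical copies, as separate genes. Of the ovary protein-coding genes beyond counting error, 12 were higher and 29 lower. The 3 listed members of the 29 interferon-response genes were also lower and beyond counting error, Isg15 at -2.06, Oas2 at -2.05 and Ifi44 at -2.00 in the authors' deposited table. Their median stood at percentile 47.9. Of the 20 uterine gland genes, 3 were listed, with the median at percentile 10.8. The thyroxine carrier gene Ttr had -2.43 in the authors' deposited table and differed beyond counting error, while Guca2b at -2.39 and Sult1d1 at 2.74 did not. None of the 47 low-oxygen response genes was listed (0 genes).

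The values in this paragraph were singled out after they were seen. Of 7 listed ovary genes annotated as ribosomal RNA, 4 were higher and 3 lower, and 1, CT010467.1, differed beyond counting error. CT010467.1 had -2.24 in the authors' deposited table on terms of 17665 to 79387. The mitochondrial leucyl-tRNA synthetase gene Lars2 had -2.41 and the short transcript Gm23935 had -2.06 in the authors' deposited table, on terms of 6601 to 33410 and 8688 to 34475. The RNA component of RNase MRP, Rmrp, had -2.89 in the authors' deposited table, and the histone gene H1f3 had -2.76.

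Among the 10 largest negative values the authors' deposited table also held Bpifb2 at -4.39, Ermn at -3.98, the protease inhibitor gene Serpinb5 at -3.88, Sun5 at -3.74, Acsbg2 at -3.66, Ccdc83 at -3.53, Scarna2 at -3.46 and H4c6 at -3.39. Among the 10 largest positive values the authors' deposited table held Ccdc7b at 3.84, Tmem239 at 3.74, Rpl30-ps2 at 3.63, Calb2 and Vmn1r157 at 3.51, the olfactory receptor gene Olfr111 at 3.39, Entpd4b at 3.38 and Mir6481 at 3.25. The last place was tied, with Syt8, Trem1 and Serpine3 at the value of Mir6481, and Krt16 likewise tied with H4c6 among the negative values. Alphabetical order decided both ties, and the tied genes Syt8, Serpine3 and Krt16 were named after their values were seen. Of the 16 genes given with values, Sun5 and Entpd4b differed beyond counting error. The others, with Csn2 and Krt6a, had a smaller term of 1 or 2, so their sizes and ranks were not fixed. With a pseudocount of 5 their positive values lay between 1.41 and 2.07 and their negative values between -2.33 and -1.56, while Entpd4b had 3.32 and Sun5 -2.85. Genes named after their values were seen included the polysialyltransferase gene St8sia2 at 2.61 and the immunoglobulin gene Ighg3 at 4.59 in the authors' deposited table, both beyond counting error. The calcium release channel gene Ryr1 was higher on terms of 4112 to 853, also beyond counting error.

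On GRCm38, Cyp19a1 lies on chromosome 9 from 54165937 to 54268110, and Cyp11b1 on chromosome 15 from 74834125 to 74841643. Krt14 lies on chromosome 11 from 100203162 to 100207548, and Krt5 on chromosome 15 from 101707070 to 101712898. Csn1s2a lies on chromosome 5 from 87774567 to 87788797, and CT010467.1 on chromosome 17 from 39846353 to 39848827.

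In all, 433 ovary genes were higher and 421 lower, and 222 were protein coding. In 621 genes (72.7%) a term was 1, the median sum of terms was 7, and 71 genes differed beyond counting error, 30 higher and 41 lower. The 144 genes with a ratio of 1 to 4 were all lower, since 4 to 1 gave 1.93; without them 433 genes were higher and 277 lower. Of the 34 lists, 22 had no listed member, 9 had 1 or 2 and 3 had 3 or more. The lists with 1 or 2 members held Cyp19a1 and Serpinb5, named by rule, and Calca, Sult1e1, Mt2, Saa3, Ccdc153, Lep, Ryr1 and Serpina1e, genes named after their values were seen.

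**Figure D2:**
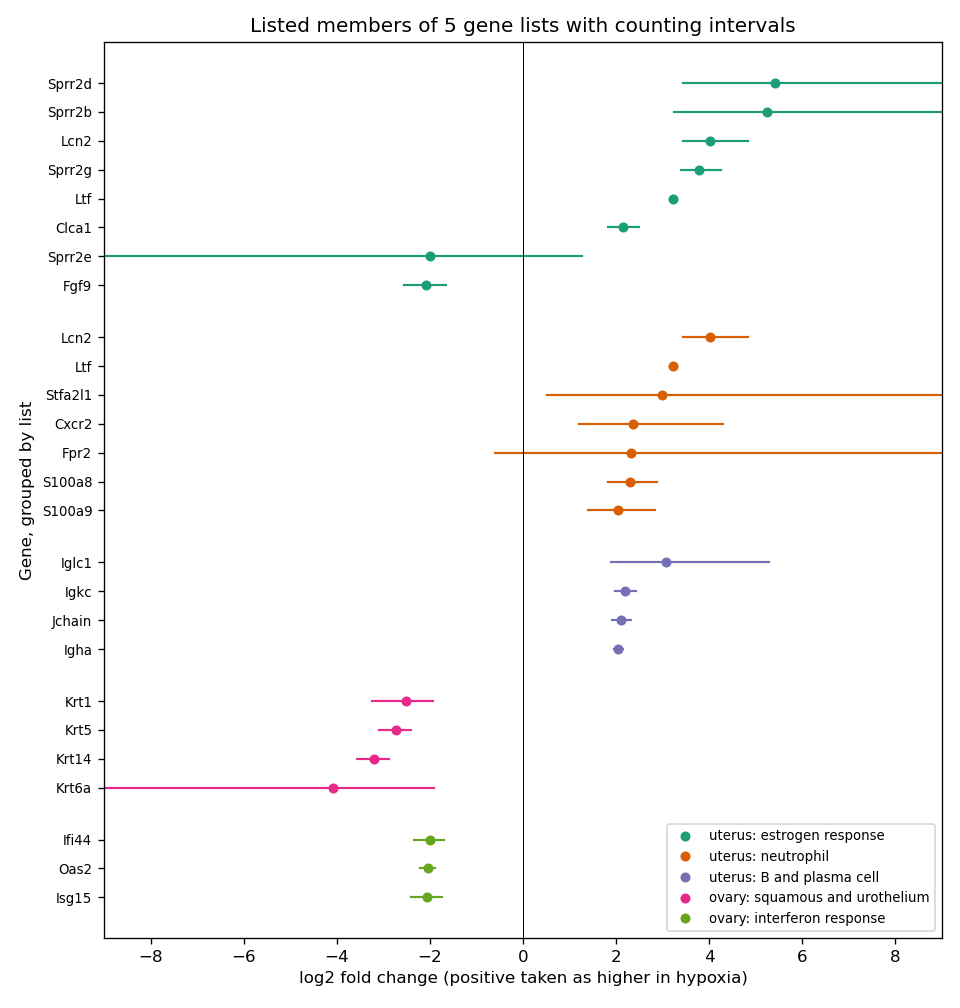
Log2 fold change (x axis, positive taken as higher in hypoxia) of the listed members of 5 gene lists (y axis), with points at the deposited values and lines for 95% counting intervals of the terms less 1, drawn to the edge where a bound is open. The 7 neutrophil genes of the uterus lie above 0 and the 4 squamous markers of the ovary lie below 0.

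The tissues shared 61 listed genes. With 1 pooled library per group, the overlap cannot tell a shared response to oxygen from other differences between the pooled animals. Of the 61 genes, 40 had the same direction, 25 higher and 15 lower in both. By each list's share of higher genes, 30.5 would match. Among protein-coding genes 11 of 19 matched, against 9.36, and without unnamed gene models 18 of 30, against 14.7. Among immunoglobulin genes 6 of 8 matched, against 6.56, and without them 34 of 53, against 26.5. The product of the list sizes over all annotated genes is 13.9, a background wider than the genes that could have been listed. Of the shared genes named by rule, the authors' deposited tables gave Trem1, a receptor of myeloid cells, 3.24 in the uterus and 3.25 in the ovary, and the immunoglobulin gene Igkv8-30 4.24 and 3.10. Ighv1-26 had 3.32 and 2.63, Iglv2 had 2.99 and 3.51, Stoml3 had 2.58 and 2.74, and Gm16838 had 2.80 and 2.51 in the authors' deposited tables. These 6 genes had a smaller term of 1 or 2 in both tissues and did not differ beyond counting error, and with a pseudocount of 5 their values lay between 0.93 and 2.19. Both lower were Rmrp, at -3.07 and -2.89 in the authors' deposited tables, and Gm43793, at -3.01 and -3.39, of which the ovary value of Rmrp differed beyond counting error. Opposite directions were listed for Calb2 and Bhmt2. The last 2 places among the 10 shared genes were tied between Bhmt2, Gm16838, Gm14419 and Igkv5-39 and were decided by rounding in the last decimals and by alphabetical order, and Gm14419 and Igkv5-39 were named after their values were seen. Only 1 shared gene, Saa3, differed beyond counting error in both tissues, and its directions were opposite, at 2.05 in the uterus and -2.64 in the ovary in the authors' deposited tables.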

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

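The sequence search for ribosomal RNA was set before its result was seen, and the other tests of explanations in this part were chosen after the values had been seen. Genes named in the text and listed in both tissues with opposite signs were picked out, and none of these differences between tissues was tested. Saa3 had 2.05 in the uterus and -2.64 in the ovary in the authors' deposited tables. Calb2 had -3.01 and 3.51, and Bhmt2 had -3.81 and 2.51, in the authors' deposited tables, and neither gene differed beyond counting error in either tissue. Serpine3 had -2.01 and 3.25, and Igkv5-39 had -3.29 and 2.51, in the authors' deposited tables, and of these 4 values the uterus value of Igkv5-39 alone was beyond counting error.

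Most listed genes had ratios of small whole numbers, which could come from counting error of few reads. On the inferred reading of the terms as counts plus 1, that cannot account for 113 uterus genes and 71 ovary genes. These differed beyond counting error after correction over all annotated genes. With the terms as counts, 107 uterus genes and 69 ovary genes did. For the genes not beyond counting error this explanation stays open. A counting interval that included a ratio of 1 was found for 414 uterus genes and 436 ovary genes. Differences between the pooled animals unrelated to oxygen could not be tested with 1 library per group. An effect of low oxygen is open on the same ground.

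Ltf, neutrophil and immunoglobulin genes were higher together in the uterus. Neutrophils as the source of the Ltf difference stay open. The S100a8 difference was 0.0105 of the Ltf difference in terms, which by the bound set for this test counted against that source. A common factor can be lost from the terms, but S100a8 would need to have lost one of at least 47.6 to reach the bound. The ratio of these RNAs in neutrophils is not measured here, so the bound cannot decide it. More antibody-secreting cells in the sampled tissue also stay open as the source of the immunoglobulin genes. The counting intervals of all 4 constant and joining chain genes held their pooled ratio of 4.23. That cannot decide it, because the ratio came from the same 4 genes, each listed only past the threshold. Of the 12 immunoglobulin genes beyond counting error, 11 were higher, with Igkv4-57 at 5.93, and 1, Igkv5-39, was lower at -3.29 in the authors' deposited table. Blood left in the sampled tissue stays open. With 0 globin genes listed, none was recorded as changed past the threshold, but smaller changes are unseen and globin levels are not analysed here. Of the 20 erythroid markers 1 was listed, Slc4a1, higher at 2.32 in the authors' deposited table and not beyond counting error. A response of the uterus to low oxygen was not tested apart from these explanations.

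CT010467.1, Lars2 and Gm23935 were lower in the ovary, while 4 of the 7 listed genes annotated as ribosomal RNA were higher, none of those beyond counting error, and reads of ribosomal RNA counted on Lars2 and Gm23935 could join the lower ones. The search found a match of at least 40 bases in 0 of these 2 genes, which by the prediction written beforehand would have counted against that explanation. The prediction was wrong in scope, as was seen only after the empty result: the longest transcript annotated as ribosomal RNA has 1849 bases, too short for large-subunit ribosomal RNA, so that part was not searched and the explanation stays open. Less RNA without a poly(A) tail in the hypoxia library also stays open. Of 4 such RNAs beyond counting error in the ovary, 3 were lower (CT010467.1, H1f3 and Rmrp) and 1, Gm25219, was higher. The same was not tested in the uterus, where Rmrp was also lower, at -3.07, and not beyond counting error. Of the small nuclear RNA genes, 10 of 11 listed were lower in the uterus and 9 of 23 in the ovary, 0 beyond counting error. An effect of low oxygen on ribosomal RNA was not tested.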

How the results depend on the processing

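Settings based on the terms, and the number of members higher, were chosen after the data were seen; the others were planned. With an absolute log2 fold change of at least 3, 150 uterus genes (97 higher, 53 lower) and 114 ovary genes (64 higher, 50 lower) were left. Without unnamed gene models the numbers were 394 (245 and 149) and 266 (122 and 144). With terms summing to at least 30 they were 136 (88 and 48) and 90 (43 and 47). Beyond counting error, with the terms less 1, they were 113 (69 and 44) and 71 (30 and 41), and with the terms as counts 107 (66 and 41) and 69 (28 and 41). Without ratios of 1 to 4, 273 uterus genes and 277 ovary genes were lower. These counts fall because each setting removes genes. The overlap was 4 genes (3 in the same direction) at the threshold of 3, 30 (18) without unnamed models, 2 (1) with terms of at least 30 and 1 (0) beyond counting error. By the median, 2 lists lay beyond the central 95% of draws, the uterine estrogen-response and the ovarian squamous list. By the mean 3 did, with the uterine neutrophil list added, which shares Ltf and Lcn2 with the estrogen-response list. By the number of members higher, 1 did, the neutrophil list, likewise 1 with draws matched on the terms; this says nothing of 5 of the 8 lists, too short to pass by it in either direction, nor of the B and plasma cell list, too short to pass by being higher. With a pseudocount of 5, which cannot turn a direction here, 37 of 84 named values fell under 2 in size and 10 left their counting interval. Not run, since the lists hold none of these, were thresholds on adjusted p, filters or matching on level, and scaling or pseudocounts from library values. No paired analysis was possible because each group has 1 library. Depth is unknown, which limits every value with small terms.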

Other observations

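The genes and classes in this part were chosen after their values were seen, and no explanation was tested. For the uterus, the authors' deposited table gave the cytochrome P450 genes Cyp3a25 -3.69, Cyp3a16 -3.08 and Cyp3a59 -2.28, each beyond counting error but uncertain because the family has near-identical copies. They lie on chromosome 5 between 145436309 and 146113287 on GRCm38. Also lower in the uterus were Gzmd, a granzyme gene, at -2.38, Procr, the endothelial protein C receptor gene, at -2.39, and Has3, a hyaluronan synthase gene, at -2.28 in the authors' deposited table. The largest positive value in the authors' deposited table of the uterus was 5.93, for the immunoglobulin kappa variable gene Igkv4-57, on terms of 306 to 5.

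Of the small nuclear RNA genes, 11 were listed in the uterus, 1 higher and 10 lower, and 23 in the ovary, 14 higher and 9 lower. In both tissues 0 of them differed beyond counting error, and the difference between the tissues was not tested. In the ovary the interferon-inducible gene Ifi202b was listed as higher, at 2.76 in the authors' deposited table, while Ifi206 and Apol9b were lower, at -2.14 each. The vanin gene Vnn3 was lower at -3.01, Bpifb6 at -2.89 and the histidine-degrading enzyme gene Hal at -2.19 in the authors' deposited table of the ovary.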
